A study of Scophthalmus maximus with 42 samples.

How the data were processed

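RNA from peritoneal cells of turbot was labelled with Cy3 and hybridised, 1 sample per array, to Agilent 1-colour arrays on slides that hold several arrays. The series has 42 arrays on 12 slides: 6 treatments, 3 days, replicates A and B of each, and a second array for every PBS replicate on another slide. The labelling protocol names 2 control and 2 treated fish per condition and time, so the 2 arrays of a PBS replicate were taken as repeats and averaged, which leaves 36 samples in 18 groups. The labels do not say whether a replicate letter stands for a shared tank or handling across treatments. Slides of the first set held PBS, antigen alone, Freund and Alum arrays, and those of the second set held the repeated PBS, Microspheres and MatrixQ arrays. Each treatment had the same place on every slide of its set. Sampling days lay on different slides and different scan days, so day and scan cannot be told apart. At day 1 the first-set slide of replicate B was scanned on another day than the other slides of day 1.

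Each scanner file holds spot intensity from Agilent Feature Extraction 9.5.1.1, per the file headers (version 9.5 per the submitters' processing notes), with 43803 non-control probes. The value table deposited by the authors holds linear whole-number intensity from 18 to 503571 for 40398 of these probes, with column medians between 329 and 335 and column 75th percentiles between 1384 and 1414.5. Its normalization is not given in the sources used here, and the columns have nearly equal medians and 75th percentiles. Between 14.9% and 36.2% of the probes have no value in a column. In the scanner file that matched a column, 99.9% of the missing values were marked not well above background.

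The scanner files and the value table disagreed on which array is which. The 6 scanner files recorded for the second PBS arrays held 0.100% to 5.19% of probes well above background, against 63.9% to 84.8% in the other 36, and their spike-in controls were dark. Of the 36 table columns whose own scanner file was hybridised, 0 matched that file best and 36 matched the file in the mirrored position of the same slide. Over 22678 probes centred on their means, the correlation with that other file was 0.906 to 0.998, and with the own file -0.255 to 0.458. In the table, the second PBS column lay closest to the first of the same replicate in 6 of 6 pairs (r of 0.800 to 0.895 over these centred probes). The value table with its own column labels was used for the results. It took the place of the scanner files that the plan made before the data were examined had named. The repeats would lie as close if the whole table were reversed, so they do not settle which order is right. At day 1, the scanner file of the first slide set matched the second PBS column of replicate B (r = 0.993) better than the first (r = 0.906), which leaves open which of these repeats lay on which slide. Values of day 1 that use the slide, or PBS arrays of either set alone, rest on the labels here.

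Probes with a value on all 42 arrays (22747) were tested. Over these, the column median rose with the number of probes listed in the column (Spearman rho 0.996 over 42 arrays), as it would if columns had been equalised over different probe sets. The arrays' 75th percentiles over these probes ranged from 10.71 to 11.35 on the log2 scale. The log2 intensity minus each array's 75th percentile over these probes was therefore used; the planned analysis had the same percentile step for the scanner signals. This scaling was chosen after the counts without scaling, and with median and quantile scaling, had been seen, and all of them are given in the closing section. No pseudocount was added. A level below is this scaled log2 intensity, which is 0 at the array's 75th percentile.

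One mean per group was fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, and p-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The fit had 18 residual degrees of freedom and a median moderated SD of 0.301 on the log2 scale. The comparisons were each vaccine against PBS at each day, the mean of the 5 vaccines against PBS at each day, the day 5 minus day 1 difference of that effect, and each adjuvanted vaccine against antigen alone over the 3 days. Added after the data were seen were 6 comparisons between adjuvanted vaccines and PBS at day 5 minus PBS at day 1. P-values rest on the spread of each probe between the 2 samples of a group, pooled over all 18 groups and moderated. They do not measure the spread in the compared groups alone, and the number of arrays limits the precision. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

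The fit was tested on simulated data with 200 changed probes among 22747. The simulated noise was independent and normal, with the same spread for a probe in all groups. It had no slide or scan structure, so recovery in the real arrays may differ. Between 5 and 14 unchanged probes were called in the comparisons simulated. For antigen alone against PBS, 29%, 28% and 32% of 2-fold changes at days 1, 3 and 5 were recovered, and 83%, 85% and 83% of 4-fold changes. For the mean of the 5 vaccines the shares were 58%, 50% and 62% of 2-fold changes and 92%, 91% and 88% of 4-fold changes. For Freund against antigen alone over the 3 days they were 78% and 95%.

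The files do not pair probes with gene names: names and descriptions repeat the probe ID, and 0 of 43803 IDs matched the RefSeq table of 26628 turbot genes. The gene lists fixed before the data were examined could not be applied and were not analysed. Probes are therefore named by ID and sequence. The planned rule took the largest changes with adjusted p under the threshold and all 10 vaccine samples on the same side of the PBS mean; because no gene names are given, it was reduced to the 2 largest rises and the 2 largest falls of each daily comparison, 1 per contig number in the ID. Its parts for single vaccines, for differences between days or from antigen alone, and for gene lists were not used. Between samples the within-slide differences from PBS were also compared, replicate A against replicate B, so that no array was shared. For day 1 this was repeated with the PBS columns of replicate B exchanged between slides, a repeat added after the data were seen.

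The alternatives were the scanner files as recorded, the scanner files given to the columns they matched with several background corrections, scalings and filters, 3 other scalings of the table, all probes of the table, a replicate block, the slide as a block, either set of PBS arrays alone, all 42 arrays as separate samples, each sample left out, and, for single vaccines against PBS, fits to only the 4 samples compared. The slide block counts the repeated PBS arrays as separate samples. Slide and replicate blocks lie within days, so they give no value for PBS at day 5 minus PBS at day 1. The labels name the oil-adjuvant group after Freund's adjuvant, while the treatment protocol and the series design name Montanide ISA 763 A; the group is called Freund here and the product it received is not settled.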

Results

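Gene expression was measured in cells washed from the peritoneal cavity of turbot (Scophthalmus maximus) of about 30 g, kept at 16 °C, at days 1, 3 and 5 after an injection into that cavity. Fish received phosphate-buffered saline (PBS), 230 µg of antigen in PBS, antigen linked to 5 mg of microspheres, or antigen mixed with an adjuvant: an oil adjuvant labelled Freund, aluminium hydroxide gel (Alum), or MatrixQ, given at 5 µg per fish. Every group had 2 samples, replicates A and B, at each day, so there were 36 samples in 18 groups. Of the 40398 probes in the authors' value table, between 25779 and 34364 had a value on an array, and 22747 had one on all 42 arrays and were compared. Directions rest on the column labels of that table, and the scanner files as recorded have the arrays of a slide in the mirrored order to it. With the scanner files as recorded, 10 of the 12 changes of single probes reported for the mean of the vaccines have the opposite sign, and only 4 of these 10, those of day 1, pass the threshold; the other 2 keep their sign and do not pass. Each treatment also had 1 fixed place on its slides, which cannot be told apart from the treatment.

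The first comparisons asked which vaccines changed expression in the peritoneal cells at day 1. Freund, Alum and Microspheres changed many of the 22747 probes against PBS: Freund gave 2799 higher and 3895 lower, Alum 3451 higher and 3810 lower, and Microspheres 3087 higher and 2533 lower. MatrixQ gave 793 higher and 289 lower, and antigen alone 269 higher and 128 lower. At least 2-fold higher and lower were 1656 and 2419 probes with Freund, 2096 and 2458 with Alum, 1844 and 1639 with Microspheres, 514 and 176 with MatrixQ, and 158 and 108 with antigen alone. Single samples moved these counts. Without PBS replicate A, Freund had 3461 calls, Alum 4143, Microspheres 2634 and MatrixQ 662, and without PBS replicate B antigen alone had 1087. Without their own replicate A, antigen alone had 11 calls, Alum 4835, Microspheres 2961 and MatrixQ 286, and without replicate B Microspheres had 3469 and MatrixQ 423. The share of calls that were higher was 54.9% for Microspheres and 73.3% for MatrixQ, and 65.7% and 89.4% without scaling of the arrays. In the matched scanner files scaled over the probes detected on all arrays, this share was 55.0% for antigen alone (67.8% in the value table, 52.9% in these files with normexp background correction), 35.5% for Alum (47.5%), 44.6% for Microspheres and 60.9% for MatrixQ.

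At day 3 fewer probes passed for all 5 vaccines. Freund gave 1515 higher and 1442 lower, Alum 1002 and 1104, Microspheres 1456 and 1301, MatrixQ 539 and 163, and antigen alone 22 and 3. At least 2-fold higher and lower were 816 and 781 probes with Freund, 697 and 677 with Alum, 934 and 748 with Microspheres, 363 and 116 with MatrixQ, and 18 and 2 with antigen alone. These counts rested strongly on single samples. Without PBS replicate B, Freund had 464 calls, Alum 278, Microspheres 234, MatrixQ 248 and antigen alone 0, and without PBS replicate A Alum had 3335 and antigen alone 13. Without their own replicate A, Freund had 709, Alum 1190, Microspheres 617, MatrixQ 19 and antigen alone 0, and without replicate B these had 1071, 563, 696, 124 and 57. With the slide as a block, MatrixQ had 449 calls and antigen alone 4. The share of calls that were higher was 47.6% for Alum, 52.8% for Microspheres and 76.8% for MatrixQ, and 37.1%, 73.2% and 91.9% without scaling. For Alum it was 64.5% in the matched scanner files with normexp background correction (860 higher and 473 lower). In the matched scanner files scaled over the probes detected on all arrays it was 42.1% for Microspheres. For Freund the share was 51.2%, and 42.6% without scaling (656 higher and 883 lower). With normexp background correction of the matched scanner files it was 60.9% for Freund (1071 higher and 687 lower).

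At day 5 the 4 adjuvanted vaccines each changed many probes, and for antigen alone none passed. Microspheres gave 2070 higher and 1501 lower, MatrixQ 2009 and 1183, Freund 1875 and 1147, and Alum 1231 and 1335. At least 2-fold higher and lower were 1397 and 751 probes with Microspheres, 1208 and 610 with MatrixQ, 1189 and 591 with Freund, and 931 and 791 with Alum. For antigen alone limma gave 0 calls, also with the slide as a block, and 5 without PBS replicate B. Of its 22747 probes, 847 had an unadjusted p under 0.05, where chance gives 1137. Differences between days in the number of calls were not tested. The 0 calls for antigen alone do not show that its response was gone. The fit pooled the spread over days. Across probes, the SD of the difference between PBS replicates was 0.807, 0.748 and 0.585 at days 1, 3 and 5. Fits to only the 4 samples compared gave Freund 0 calls at day 1 and 1720 at day 5. Microspheres had 656 and 2322 in these fits, Alum 228 and 2, and MatrixQ and antigen alone 0 at both days. Without PBS replicate A, Freund had 1181 calls, Alum 522, Microspheres 1080 and MatrixQ 1018, and without PBS replicate B they had 972, 1521, 1529 and 1577. Without their own replicate A they had 670, 300, 1184 and 1062, and without replicate B Freund had 1184, Microspheres 862 and MatrixQ 1586. The share of calls that were higher was 62.0% for Freund, 48.0% for Alum, 58.0% for Microspheres and 62.9% for MatrixQ. Without scaling it was 84.7%, 69.7%, 88.0% and 80.4%, and with the median as the scale it was 46.2% for Microspheres.

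**Figure D1:**
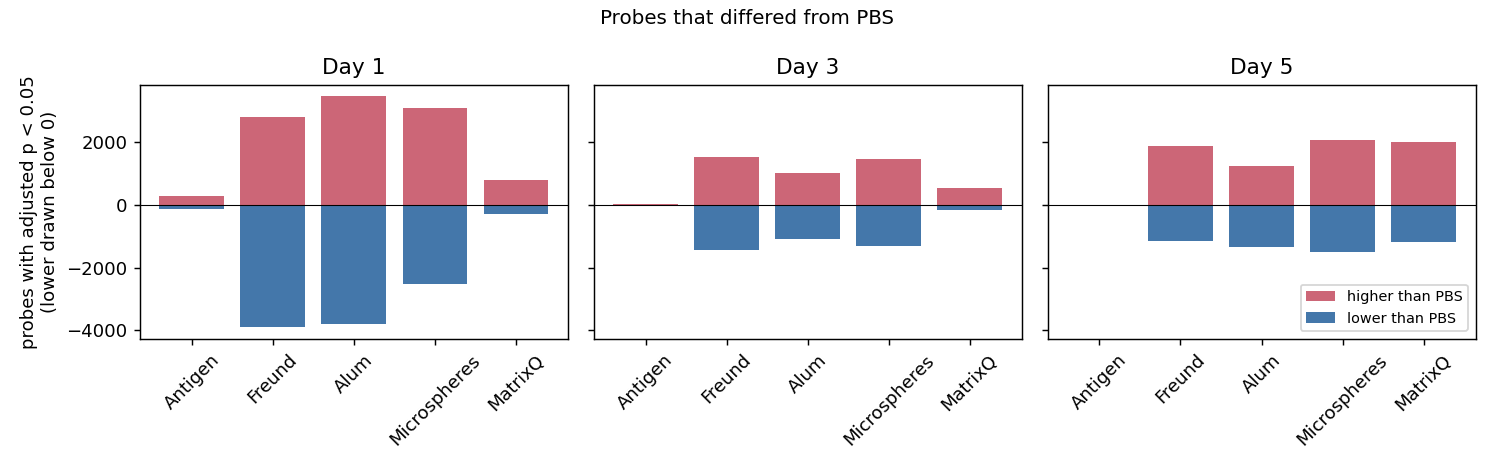
Bars give the number of probes higher (above 0) and lower (below 0) than PBS with adjusted p under 0.05 in limma, for each of 5 vaccines at days 1, 3 and 5, with 2 samples per group. Antigen alone has 397 at day 1 and 0 at day 5, and Alum at day 1 has 3451 higher and 3810 lower.

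Replicates A and B were then set against each other as differences from the PBS array on the same slide, which share no array. Across probes, which are not independent replicates, r at day 1 was 0.610 for Freund, 0.600 for Alum, 0.608 for Microspheres, 0.115 for antigen alone and 0.101 for MatrixQ. At day 3 r was 0.520 for Freund, 0.229 for Alum, 0.415 for Microspheres, 0.421 for MatrixQ and 0.219 for antigen alone. At day 5 it was 0.672 for Freund, 0.644 for Alum, 0.714 for Microspheres, 0.611 for MatrixQ and 0.315 for antigen alone. The part of the difference from PBS that both replicates shared, taken as the square root of their covariance, was 0.751 on the log2 scale for Freund at day 1, 0.793 for Alum and 0.716 for Microspheres, against 0.257 for antigen alone and 0.233 for MatrixQ. At day 5 this value for MatrixQ was 0.601, for Microspheres 0.686 and for antigen alone 0.287. Which PBS array of replicate B lay on which slide at day 1 is open. With these exchanged, r at day 1 was 0.654 for Freund, 0.641 for Alum, 0.621 for Microspheres, 0.123 for antigen alone and 0.124 for MatrixQ, and the shared part was 0.779, 0.840, 0.705, 0.252 and 0.252.

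**Figure D2:**
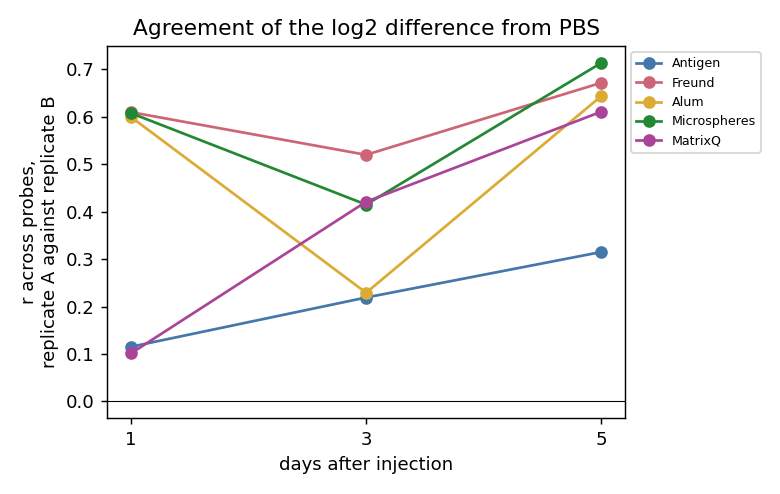
Points give r across 22747 probes between replicates A and B of the log2 difference from the PBS array of the same slide (vertical axis), by days after injection (horizontal axis), with 1 line per vaccine. MatrixQ goes from 0.101 at day 1 to 0.611 at day 5, and antigen alone from 0.115 to 0.315.

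Differences from PBS were also compared between vaccines. Replicate A of one vaccine against replicate B of another gave a mean r at day 1 of 0.505 for Freund and Alum, 0.467 for Freund and Microspheres, and 0.523 for Alum and Microspheres, while MatrixQ with these 3 gave 0.171, 0.185 and 0.150. Antigen alone gave -0.019 with Freund, 0.081 with Alum, 0.128 with Microspheres and -0.015 with MatrixQ at day 1. With the PBS arrays of replicate B exchanged, r at day 1 was 0.459 to 0.550 among Freund, Alum and Microspheres, 0.123 to 0.155 between these and MatrixQ, and -0.020 to 0.145 between antigen alone and the others. At day 3 antigen alone gave 0.137, -0.040, 0.056 and 0.127 in the same order, and at day 5 0.261, 0.192, 0.231 and 0.284. At day 5 MatrixQ gave 0.507 with Freund, 0.503 with Alum and 0.517 with Microspheres. The low agreement between their own replicates limits these r for MatrixQ at day 1 (0.101) and for antigen alone, so they do not show how alike the responses were, and no difference between them was tested. Freund, Alum and Microspheres shared 1311 higher and 1705 lower calls at day 1. Independent lists of these lengths would share 57.6 and 72.7, and part of the excess may come from the shared controls. Unchanged groups simulated against the same PBS samples shared 0, but they had on average 0.0167 higher and 0.0667 lower calls each, so this does not measure what shared controls add. All 5 vaccines shared 102 higher and 27 lower calls at day 1, 5 and 1 at day 3, and 0 at day 5, where antigen alone had 0 calls.

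The mean of the 5 vaccines against PBS averages their differences, so a probe can pass when only some of the vaccines changed it. In limma at day 1, 2712 probes were higher and 2574 lower in 10 vaccine samples against 2 PBS samples. Among probes with all 10 vaccine samples on the same side of the PBS mean, the largest rise was that of R4_56095.1 (55 bases, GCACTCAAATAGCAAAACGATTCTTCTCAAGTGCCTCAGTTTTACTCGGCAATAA), from -5.28 ± 0.17 in PBS (SD, n = 2) to -0.78 ± 1.19 with vaccine (SD, n = 10), a log2 difference of 4.50 ± 0.40 (SE) with limma's adjusted p = 8.07e-07. It rose with every vaccine at day 1, by 2.79 on the log2 scale with antigen alone and by 5.76 with MatrixQ. Its level in PBS was lowest at day 1. In PBS it was -1.36 and -3.18 at day 3, and -2.07 and -0.68 at day 5. The difference of R4_56095.1 was 1.62 at day 3, and 0.92 at day 5, which did not pass. R4_66010 (56 bases, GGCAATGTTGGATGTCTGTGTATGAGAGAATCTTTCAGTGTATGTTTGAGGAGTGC) rose by 3.94 ± 0.44 (SE), adjusted p = 6.93e-06 in limma, with all vaccines but antigen alone past the threshold. R4_3173.1 (55 bases, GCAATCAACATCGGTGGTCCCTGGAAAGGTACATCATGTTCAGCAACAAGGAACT) fell from 2.85 ± 0.49 (SD, n = 2) to -0.97 ± 1.14 (SD, n = 10), a difference of -3.82 ± 0.51 (SE), limma's adjusted p = 3.70e-05. R4_58563 (55 bases, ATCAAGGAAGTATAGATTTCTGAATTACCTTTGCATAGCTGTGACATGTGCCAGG) fell by 3.40 ± 0.40 (SE), adjusted p = 1.12e-05 in limma, and its difference was -0.15 at day 3 and -0.16 at day 5, neither past the threshold. Both falls passed with every single vaccine at day 1. The level of R4_58563 in PBS was 0.86 and -1.04 at day 1, and lay between -2.54 and -1.28 at days 3 and 5. With vaccine at day 1 it was -3.49 on average. R4_3173.1 in PBS was 2.51 and 3.20 at day 1, 1.08 and 1.39 at day 3, and 2.21 and 3.52 at day 5. Its mean difference at day 3 was -1.27, which did not pass. The probes named for days 3 and 5 also had all 10 vaccine samples on the same side. With the slide as a block the count at day 1 was 8260, and without PBS replicate A it was 1418. The slide block counts the repeated PBS arrays as separate samples. With all 42 arrays as separate samples and no slide block the count was 8454, so the larger count cannot be put down to the slide. The share that was higher was 51.3%, and 38.3% in the matched scanner files scaled over the probes detected on all arrays.

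At day 3 the mean of the vaccines had 1213 probes higher and 857 lower. R4_51991.1 (55 bases, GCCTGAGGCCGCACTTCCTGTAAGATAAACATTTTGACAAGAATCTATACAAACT) rose by 4.06 ± 0.66 (SE), adjusted p = 0.00200 in limma, with single-vaccine differences of 1.21 for antigen alone, which did not pass, and 3.94 to 5.55 for the 4 adjuvanted vaccines, which did. R4_3140r (56 bases, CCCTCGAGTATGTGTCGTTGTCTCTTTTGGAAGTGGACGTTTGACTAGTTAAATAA) rose by 3.74 ± 0.68 (SE), adjusted p = 0.00377 in limma, with 0.96 for MatrixQ and 3.96 for antigen alone, neither of which passed. R4_10759 (55 bases, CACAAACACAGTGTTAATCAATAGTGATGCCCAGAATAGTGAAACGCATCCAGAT) fell by 2.17 ± 0.55 (SE), and R4_29779 (56 bases, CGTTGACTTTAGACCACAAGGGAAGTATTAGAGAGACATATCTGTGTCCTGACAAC) fell by 2.10 ± 0.49 (SE), with limma's adjusted p = 0.0186 and 0.0123. R4_10759 passed with Freund, Alum and Microspheres, but not with antigen alone (adjusted p = 0.705) or MatrixQ (0.338). R4_29779 passed with Alum and Microspheres, but not with Freund (0.153), MatrixQ (0.186) or antigen alone (0.260). This day rested on 1 control: without PBS replicate B the count was 48, and none of these 4 probes passed, with adjusted p between 0.130 and 0.293. In that fit the log2 differences kept their sign and were smaller, at 2.94 for R4_51991.1, 2.99 for R4_3140r, -1.76 for R4_10759 and -1.86 for R4_29779. With the slide as a block, which counts repeated PBS arrays as samples, the count was 5109. All 42 arrays as separate samples with no slide block gave 5810. The share that was higher was 58.6%, and 47.0% in the matched scanner files scaled over the probes detected on all arrays.

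At day 5 there were 1968 probes higher and 1348 lower. R4_13126.1 (55 bases, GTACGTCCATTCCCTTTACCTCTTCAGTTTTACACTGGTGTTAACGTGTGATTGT) rose from -3.19 ± 1.42 in PBS (SD, n = 2) to 2.37 ± 2.19 (SD, n = 10), a difference of 5.56 ± 0.48 (SE), adjusted p = 1.52e-06 in limma. Its difference was 8.31 with Microspheres, 7.12 with Freund, 5.49 with MatrixQ and 4.42 with Alum, all past the threshold, and 2.44 with antigen alone, which was not. R4_52233 (55 bases, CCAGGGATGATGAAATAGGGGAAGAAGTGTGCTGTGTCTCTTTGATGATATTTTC) rose by 4.50 ± 0.63 (SE), adjusted p = 2.15e-04 in limma. R4_18633 (55 bases, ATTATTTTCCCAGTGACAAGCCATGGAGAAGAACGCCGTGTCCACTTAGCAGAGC) fell from -1.15 ± 0.03 (SD, n = 2) to -3.77 ± 1.37 (SD, n = 10), a difference of -2.63 ± 0.32 (SE), limma's adjusted p = 8.85e-05, with a value of -0.14 for antigen alone and -2.83 to -3.74 for the adjuvanted vaccines. At this day R4_3173.1 also fell by 2.62 ± 0.51 (SE), adjusted p = 0.00245 in limma, and did not pass without PBS replicate B (adjusted p = 0.0969). These 4 probes passed with each adjuvanted vaccine. They did not pass with antigen alone, where no probe passed at this day. With antigen alone the difference was 1.37 for R4_52233 and -1.72 for R4_3173.1. At day 3 the level of R4_52233 was 6.798 and 5.039 with antigen alone, against 1.625 and 1.057 in PBS. In the mean of the vaccines, R4_13126.1 also passed at days 1 and 3, with differences of 3.785 and 2.849. R4_18633 passed at these days too, with -2.316 and -2.427, while R4_52233 did not, with 1.103 and 1.23. Adjuvanted vaccines were not tested against antigen alone at day 5 by itself. The count was 412 without PBS replicate A, 828 without PBS replicate B and 6790 with the slide as a block. The slide block counts repeated PBS arrays as samples, and all 42 arrays as separate samples with no slide block gave 7132. The share that was higher was 59.3%, and 84.2% without scaling (2227 higher and 418 lower).

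**Figure D3:**
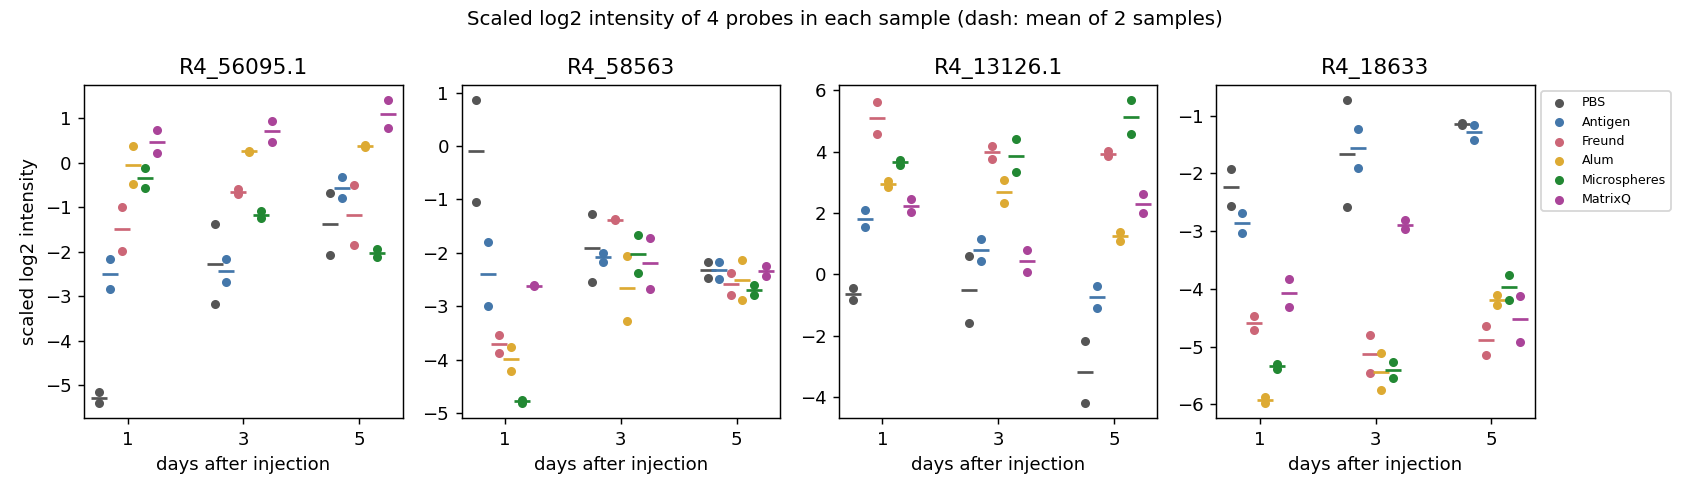
Each point is 1 sample's scaled log2 intensity (vertical axis; 0 is the array's 75th percentile) by days after injection, for PBS and 5 vaccines, and each dash is the mean of 2 samples. R4_56095.1 in PBS lies at -5.28 at day 1, and R4_18633 lies at -1.15 in PBS at day 5 and at -3.77 on average with vaccine.

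Most of what changed at day 3 was also called at another day in the same direction. Of the 1213 probes higher at day 3, 576 were higher at day 1 and 752 at day 5, where independent lists would share 144.6 and 104.9. Of the 857 lower at day 3, 545 were lower at day 1 and 490 at day 5, against 97.0 and 50.8 for independent lists. Different PBS samples served each day. Between days 1 and 5, 647 higher and 746 lower calls were shared, while 23 and 86 went the opposite way. The difference in the mean vaccine effect between day 5 and day 1 passed for 961 probes, 516 higher and 445 lower at day 5. That count was 635 without PBS replicate A of day 5, 180 without PBS replicate B of day 5 and 3100 with the slide as a block. The slide block counts repeated PBS arrays as samples, and all 42 arrays as separate samples with no slide block gave 3750. The share that was higher was 53.7%, 71.3% without scaling, and 70.9% in the matched scanner files scaled over the probes detected on all arrays.

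**Figure D4:**
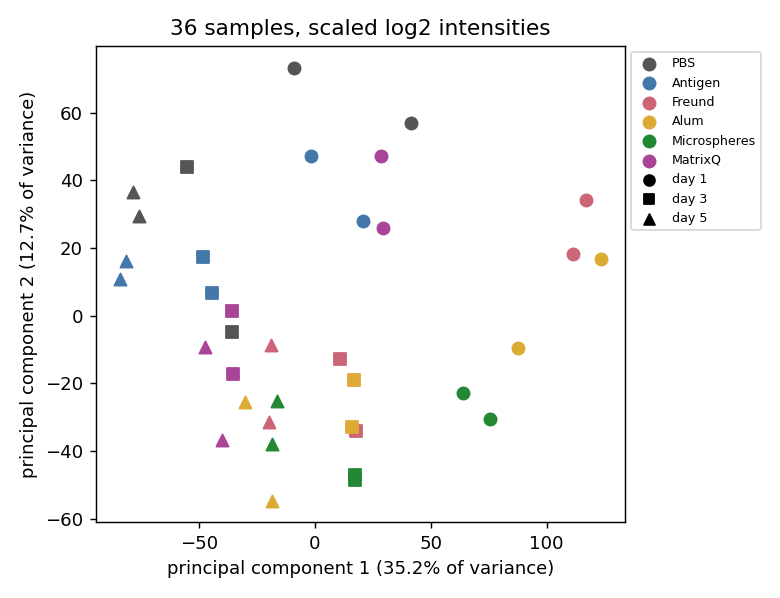
Each point is 1 of 36 samples on principal component 1 (35.2% of the variance, horizontal axis) and component 2 (12.7%, vertical axis) of scaled log2 intensity, coloured by treatment and shaped by day. Freund and Alum samples of day 1 lie between 87.7 and 123.3 on component 1, and PBS samples of day 5 at -78.6 and -76.0.

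The last question was what each adjuvant or carrier added to the antigen, over the 3 days, with 6 samples against 6. Against antigen alone, Alum had 3230 probes higher and 5347 lower, Freund 2949 and 4368, Microspheres 3357 and 3598, and MatrixQ 1055 and 719. At least 2-fold higher were 1371, 1108, 1210 and 316, in this order, and at least 2-fold lower 959, 802, 722 and 130. Freund, Alum and Microspheres shared 1687 higher and 2345 lower calls, where independent lists would share 61.8 and 162, and part of the excess may come from the shared antigen samples. Simulated unchanged groups shared 0 but had almost no calls to share (0.0167 higher and 0.0333 lower on average). Freund and Alum arrays lay on the slides of the antigen arrays, and with the slide as a block they gave 7029 and 8457 calls. Microspheres and MatrixQ arrays lay on other slides, linked only by PBS, and gave 2588 and 122 calls with the slide as a block. Such a link lowers the precision of these 2 comparisons, so the lost calls need not come from the slides. MatrixQ had 1174 calls without its replicate A of day 1, 1024 without its replicate A of day 3 and 1123 without antigen replicate B of day 3. The share of calls that were higher was 37.7% for Alum and 48.3% for Microspheres, and 49.1% and 60.01% in the matched scanner files with normexp background correction. Without scaling it was 73.0% for Microspheres (4405 higher and 1626 lower). For MatrixQ it was 59.5%, and 85.8% without scaling (1405 higher and 233 lower), 45.2% with the median as the scale and 49.5% after quantile normalization, with 99 higher and 23 lower under the slide block.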

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

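The tests of array order, of the slide sets and of other splits of the samples, and the scaling of the arrays, were chosen only after the results they bear on had been seen.

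The vaccine effect, as the mean of 5 vaccines against PBS, differed between day 5 and day 1 for 961 probes, 516 higher and 445 lower at day 5, by a test of the difference itself in limma. PBS alone differed between these days for 6280 probes, 3491 higher and 2789 lower at day 5, but 2000 higher and 3126 lower in the matched scanner files with normexp background correction. That PBS count was 3532 without replicate B of day 1 and 3305 without replicate B of day 5. The 961 rest on the PBS samples of day 5: the count was 180 without PBS replicate B of day 5 and 635 without replicate A. No slide and no scan day held arrays of more than 1 sampling day, so a difference between days cannot be told apart from one between scans, and no biological explanation was tested.

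The value table and the scanner files differed in which array is which. In 36 of 36 columns the best match was the file at the mirrored position of the slide, a candidate explanation being that the scanner files were recorded in reversed order within each slide. An error in only the first or only the second PBS columns is argued against by the repeats, which lay closest to their own replicate in 6 of 6 pairs. A reversal of the whole table, with the scanner files right, stays open. It would give the second PBS column the array at the mirrored position of its slide, for which the series has no file. The 6 dark files recorded for the second PBS arrays therefore do not exclude it. Both PBS columns of a replicate would move to the same mirrored position, so the repeats cannot tell such a reversal from right labels.

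The calls at day 5 were mostly rises before scaling (84.2%). Scaling may account for part of this: over the same probes of the table the share was 59.35% at the 75th percentile, 50.4% with the median and 53.2% after quantile normalization. In the matched scanner files, which test other probes, it was 62.9% at the 75th percentile and 58.8% after quantile normalization. Scaling also removes a rise that most probes share, so such a rise stays open. With either set of PBS arrays alone the unscaled share was at least 73.7%, so rises stayed the larger part with both. At the 75th percentile the share was 63.6% with the first set and 54.4% with the second. Both sets are arrays of the same PBS samples, so this does not test whether these controls account for the rises. The number of probes listed in a column tracked the column's median over common probes, with a Spearman rho of 0.996 over 42 arrays.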

How the results depend on the processing

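Alternatives with matched scanner files and with other scalings of the table were chosen after seeing the data; the others were set before. The counts of probes past the threshold in limma for 30 comparisons are given here where they moved by over 1.5 times from the value reported; the cause was not tested unless named. In the matched scanner files with normexp background correction the counts were 119 for antigen at day 1, 3653 for Microspheres at day 1, 648 for MatrixQ at day 1, 0 for antigen at day 3, 1758 for Freund at day 3, 1333 for Alum at day 3, 353 for MatrixQ at day 3, 1845 for Freund at day 5, 2001 for MatrixQ at day 5, 1214 for the mean of vaccines at day 3, 2203 for the mean of vaccines at day 5, 508 for the day 5 minus day 1 effect and 756 for Freund against Alum. In the matched scanner files with no filter on dim probes they were 189 for antigen at day 1, 0 for antigen at day 3 and 457 for MatrixQ at day 3. With all probes of the table, missing values included, they were 215 for antigen at day 1 and 0 for antigen at day 3. Without scaling of the table they were 110 for antigen at day 1, 0 for antigen at day 3, 1539 for Freund at day 3, 1213 for Alum at day 3, 1021 for the mean of vaccines at day 3, 509 for the day 5 minus day 1 effect, 609 for Freund against Alum and 3074 for Alum against Microspheres. With all 42 arrays as separate samples, which counts repeats as samples, they were 1606 for antigen at day 1, 2254 for MatrixQ at day 1, 215 for antigen at day 3, 5077 for Freund at day 3, 4166 for Alum at day 3, 5001 for Microspheres at day 3, 1988 for MatrixQ at day 3, 5200 for Freund at day 5, 4624 for Alum at day 5, 5756 for Microspheres at day 5, 5294 for MatrixQ at day 5, 8454 for the mean of vaccines at day 1, 5810 for the mean of vaccines at day 3, 7132 for the mean of vaccines at day 5, 3750 for the day 5 minus day 1 effect and 10276 for PBS at day 5 against day 1. Fits to only the 4 samples compared, which have fewer degrees of freedom, gave 0 for antigen at day 1, 0 for Freund at day 1, 228 for Alum at day 1, 656 for Microspheres at day 1, 0 for MatrixQ at day 1, 0 for antigen at day 3, 0 for Freund at day 3, 0 for Alum at day 3, 0 for Microspheres at day 3, 0 for MatrixQ at day 3, 1720 for Freund at day 5, 2 for Alum at day 5, 2322 for Microspheres at day 5 and 0 for MatrixQ at day 5. The matched scanner files at the 75th percentile gave 0 for antigen at day 3. With quantile normalization these files gave 14 for antigen at day 3 and 4021 for Alum at day 5. With the percentile taken over probes detected on all arrays these files gave 0 for antigen at day 3, 3293 for Alum at day 3, 3998 for Alum at day 5, 1586 for the day 5 minus day 1 effect, 2111 for Freund against Alum, 2833 for Alum against Microspheres and 7204 for Microspheres against MatrixQ. With only probes well above background on all arrays these files gave 6 for antigen at day 3. The table scaled to the median gave 8 for antigen at day 3. Quantile normalization of the table gave 11 for antigen at day 3. With the slide as a block the counts were 4 for antigen at day 3, 449 for MatrixQ at day 3, 8260 for the mean of vaccines at day 1, 5109 for the mean of vaccines at day 3, 6790 for the mean of vaccines at day 5, 3100 for the day 5 minus day 1 effect, 2588 for Microspheres against antigen, 122 for MatrixQ against antigen, 30 for Freund against Microspheres, 1053 for Freund against MatrixQ, 2 for Alum against Microspheres and 2097 for Alum against MatrixQ. The slide-block fit also counts repeats as samples. The first PBS arrays alone gave 7 for antigen at day 3. The second PBS arrays alone gave 16 for antigen at day 3. In the scanner files as recorded they were 1675 for Microspheres at day 3, 0 for MatrixQ at day 3, 417 for antigen at day 5, 147 for Microspheres at day 5, 308 for MatrixQ at day 5, 831 for the mean of vaccines at day 3, 1017 for the mean of vaccines at day 5, 606 for the day 5 minus day 1 effect, 476 for Freund against Alum, 2374 for Freund against Microspheres, 10098 for Freund against MatrixQ, 6497 for Alum against Microspheres, 13450 for Alum against MatrixQ and 12001 for PBS at day 5 against day 1.

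With each sample left out in turn, which leaves a lone sample assumed to vary like the other groups, the counts ranged from 11 to 1087 for antigen at day 1, from 3461 to 7626 for Freund at day 1, from 4143 to 7839 for Alum at day 1, from 2634 to 6450 for Microspheres at day 1, from 286 to 1613 for MatrixQ at day 1, from 0 to 57 for antigen at day 3, from 464 to 3970 for Freund at day 3, from 278 to 3335 for Alum at day 3, from 234 to 4003 for Microspheres at day 3, from 19 to 888 for MatrixQ at day 3, from 0 to 5 for antigen at day 5, from 670 to 1184 for Freund at day 5, from 300 to 2064 for Alum at day 5, from 862 to 1529 for Microspheres at day 5, from 1018 to 1586 for MatrixQ at day 5, from 1418 to 5880 for the mean of vaccines at day 1, from 48 to 3046 for the mean of vaccines at day 3, from 412 to 3225 for the mean of vaccines at day 5, from 180 to 1431 for the day 5 minus day 1 effect, from 6244 to 6822 for Freund against antigen, from 6894 to 9480 for Alum against antigen, from 5540 to 6711 for Microspheres against antigen, from 1024 to 1353 for MatrixQ against antigen, from 569 to 2570 for Freund against Alum, from 642 to 1157 for Freund against Microspheres, from 4376 to 5183 for Freund against MatrixQ, from 254 to 4751 for Alum against Microspheres, from 5600 to 9022 for Alum against MatrixQ, from 3463 to 4357 for Microspheres against MatrixQ and from 3305 to 6446 for PBS at day 5 against day 1. Of these counts, 83 moved by over 1.5 times and 161 did not.

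The 12 changes of single probes kept their sign and call under the alternatives run for them, except the scanner files as recorded and 5 values from fits that left out a sample. These probes were picked from the same arrays as the largest changes past the threshold. Stability under other processing was thus likely in advance and is no independent support, and the sizes of the changes may be overstated. Fits to only the 4 samples compared were run for counts of single vaccines and not for these probes. In the scanner files as recorded the log2 differences were -1.89 for R4_56095.1 at day 1, -1.62 for R4_66010 at day 1, 2.24 for R4_3173.1 at day 1, 1.34 for R4_58563 at day 1, -2.54 for R4_51991.1 at day 3, -1.31 for R4_3140r at day 3, 1.43 for R4_10759 at day 3, 1.29 for R4_29779 at day 3, 1.05 for R4_18633 at day 5 and 0.65 for R4_3173.1 at day 5, all with the sign opposite to that reported. Of these the 4 of day 1 passed, and the others did not, with adjusted p of 0.0501 for R4_51991.1, 0.369 for R4_3140r, 0.201 for R4_10759, 0.192 for R4_29779, 0.0672 for R4_18633 and 0.554 for R4_3173.1 at day 5. The differences were 0.15 for R4_13126.1 and 0.19 for R4_52233, which did not pass either (adjusted p = 0.924 and 0.932). Without PBS replicate B of day 3, the 4 probes of that day did not pass (adjusted p of 0.130, 0.148, 0.293 and 0.220), nor did R4_3173.1 at day 5 without PBS replicate B of that day (0.0969).

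With the replicate letter as a block, 0 of 29 counts moved by over 1.5 times: 5456, 2164 and 3585 for the mean of vaccines at days 1, 3 and 5. The differences of replicates A and B of 45 pairs of groups of a day correlated across probes at -0.401 to 0.532 (median 0.219). Within a day and slide set each replicate letter lay on its own slide. These values thus do not exclude a part shared by the samples of a letter. The letters were not taken to pair samples in the main fit. Slide and replicate blocks lie within days, so neither gave a count for PBS at day 5 against day 1. Gene lists and camera were not run because the probes have no gene names, and the planned settings for scanner files were run on the matched files only. Signal over background limits the tests to probes with values on every array.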

Other observations

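The comparisons between adjuvanted vaccines, the slide-set test and the counts of other splits were chosen only after the results were seen.

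Over the 3 days, with 6 samples against 6 in limma, Alum and MatrixQ differed at 7726 probes (2600 higher and 5126 lower with Alum), Freund and MatrixQ at 5682 (2143 higher and 3539 lower with Freund), and Microspheres and MatrixQ at 4708 (2156 higher and 2552 lower with Microspheres). Freund and Alum differed at 1339 (622 higher and 717 lower with Freund), Freund and Microspheres at 1395 (677 and 718), and Alum and Microspheres at 1853 (719 and 1134). At least 2-fold were 76 higher and 280 lower probes between Freund and Alum, against 1056 and 731 between Alum and MatrixQ. The last 3 counts rest on single samples: leaving out 1 of 12 moved them by over 1.5 times for 9, 10 and 9 of the samples, to between 569 (without Alum replicate A of day 5) and 2570 (without Alum replicate B of day 1), 642 and 1157, and 254 (without Alum replicate A of day 1) and 4751 (without Alum replicate B of day 1). The share that was higher depended on the scaling. It was 38.8% for Alum against Microspheres, 10.7% without scaling and 64.1% with the median as the scale, and for Freund against Microspheres it was 48.5%, 12.1% and 68.2%. For Freund against MatrixQ it was 37.7%, 21.4% and 48.7%, and for Alum against MatrixQ 33.7%, 22.3% and 43.8%. For Freund against Alum it was 46.5%, 31.2% and 43.95%, and 61.4% in the matched scanner files scaled over the probes detected on all arrays. For Microspheres against MatrixQ it was 45.8%, 53.7% and 45.02%. In the matched scanner files with normexp background correction the balance turned for 5 of the pairs: 59.7% for Microspheres against MatrixQ, 52.5% for Freund against MatrixQ, 51.9% for Alum against MatrixQ, 55.7% for Alum against Microspheres and 53.2% for Freund against Microspheres.

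Freund and Alum arrays lay on other slides than Microspheres and MatrixQ arrays, so a difference between the slide sets may enter these comparisons. With the slide as a block, Alum and Microspheres differed at 2 probes, Freund and Microspheres at 30, Freund and MatrixQ at 1053 and Alum and MatrixQ at 2097. Against MatrixQ the balance turned for Freund, with 647 probes higher and 406 lower, and for Alum, with 1159 higher and 938 lower. It also turned for Freund against Microspheres, with 25 higher and 5 lower. For Microspheres against MatrixQ it did not turn, with 2033 higher and 2265 lower. The pairs on the same slides, Freund with Alum and Microspheres with MatrixQ, differed at 1387 and 4298. Pairs across the slide sets are linked in this fit only by the PBS arrays, which lowers their precision. Their lost calls therefore need not be differences between slides. The difference between second and first PBS arrays correlated across probes at r = 0.203 with the difference between the vaccines of the second and the first slide set, and limma found 0 of 22747 probes different between the paired PBS arrays (6 pairs). These values leave the slide sets and the vaccines unseparated, since r lay between the bounds set for either answer.

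Of the 108 splits of the 12 samples within days, 100 were drawn. Against antigen alone, 1 split, the real one, gave as many calls for each vaccine: Freund 7317 with a highest other of 4296, Alum 8577 with 4903, Microspheres 6955 with 2913, and MatrixQ 1774 with 611. The same held, with 1 split, for Freund and Microspheres (1395, highest other 559), Freund and MatrixQ (5682 and 4076), Alum and Microspheres (1853 and 470), Alum and MatrixQ (7726 and 5236), and Microspheres and MatrixQ (4708 and 2709). For Freund and Alum 2 splits gave as many, the real one with 1339 and another with 3057. The other parted the vaccines at days 3 and 5 but replicate A from B at day 1, where the replicates lay on different slides scanned on different days. These samples thus have a structure beside the vaccine, whose cause was not tested, and the count for this pair with the slide as a block was 1387. In every pair the highest other split parted the vaccines as the real one does on most days and mixed them on the remaining day. The highest other counts thus hold much of the real difference and do not measure chance alone. For each count taken alone, the share of drawn splits with as many calls was under 0.05, with no correction for the 10 counts. A chance split leaves out a difference between slides, so these shares do not show that the vaccine made the difference. For Freund and Alum, a split other than that of the vaccines gave more calls than the real one.

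Some probes had values on both arrays of a vaccine and on neither first array of PBS, or the reverse. For Alum, Freund and antigen alone the balance turned at day 5, while for Microspheres and MatrixQ the first kind was more frequent at every day. Differences between days were not tested. At day 1 these were 813 and 163 for Microspheres, 758 and 44 for MatrixQ, 256 and 329 for Alum, 168 and 376 for Freund, and 138 and 244 for antigen alone. At day 3 they were 1347 and 118 for Microspheres, 1228 and 86 for MatrixQ, 124 and 356 for Alum, 137 and 215 for Freund, and 94 and 165 for antigen alone. At day 5 these were 2205 and 17 for Microspheres, 1207 and 25 for Alum, 1126 and 67 for MatrixQ, 832 and 24 for Freund, and 454 and 50 for antigen alone. The second PBS arrays against the first gave 42 and 204 at day 1, 159 and 59 at day 3, and 592 and 7 at day 5. The first PBS arrays lay on the slides of antigen alone, Freund and Alum, and on other slides than Microspheres and MatrixQ. The number of probes with a value also differed between arrays of 1 sample. For PBS replicate B at day 5 it was 26902 on the first array and 31183 on the second. These counts thus do not separate vaccine or day from the arrays.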
